A study of Saccharomyces cerevisiae with 14 samples.

How the data were processed

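Total RNA from Saccharomyces cerevisiae was labelled with 33P by reverse transcription and hybridised to gene membranes. Per the labels, cultures in mid log phase were split into aliquots that were mock-treated or treated with methyl methanesulfonate (MMS), a DNA-alkylating agent, at 0.00125% or 0.0125%. Strain FF18984 was grown in minimal F1 medium and in rich YPD medium and sampled after 30 min and after 1 h, which gives 12 arrays. Strain BY4742 was grown in YPD with 0.0125% MMS or mock for 1 h, which gives 2 arrays. Each condition has 1 array. Per the labels, the samples of 1 medium and time were hybridised in turn to the same membrane, which was stripped in between, so that the 14 arrays form 5 membrane sets. The order of the hybridisations is not given, nor whether the 30 min and 1 h samples of a medium came from 1 culture.

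The deposited files give an intensity per spot, as the spot integral, its local background and their difference, per the file headers. They cover 6912 positions with 2 spots each, of which 6102 positions carry an open reading frame. These are 6094 distinct open reading frames, 8 of them on 2 positions. Gene symbols were taken from the reference gene table for 5567 of them, and 527 kept the name in the files. A further 125 positions had a name but no open reading frame, and 685 had neither. No positions on the genome are given, since the files name no genome build. The authors also deposited a series table of intensity values, in which each array had a lowest value shared by many genes. The labels do not say how this table was made. Its values for the strongest genes followed the spot files in a straight line on 13 of the 14 arrays. No normalization between the arrays was applied by the authors to the spot files, and the software used is not stated.

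The deposited background-subtracted intensity of both spots was used. The scale of the files differs by orders of magnitude, with a median signal from 41.7 to 2018610. Each array was therefore first divided by its own median positive value, a step added to the plan once the files had been seen. Values below 0 were set to 0 and a pseudocount of 0.187 was added, the 10th percentile of all positive values on that scale. Log2 values of the spots of a gene were averaged, and the arrays were quantile normalized in limma 3.58.1 under R 4.3.3. No gene was left out. Between 2.57% and 33.4% of genes per array had a signal of 0 or less, and the Spearman correlation across genes between the spots of a pair was 0.675 to 0.939. The number of arrays limits the precision.

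Dose was tested in limma (lmFit, eBayes with trend) on the 12 FF18984 arrays with membrane set as a block, so that the spread is the disagreement between the 4 sets. Separate fits added dose by time or dose by medium. YPD was compared with F1 with time and dose in the fit and membrane set as a random block (duplicateCorrelation, statmod 1.5.0). Genes passed at a Benjamini-Hochberg adjusted p under 0.05 over all 6094 genes. The p-values measure only the spread between these samples, since the labels do not state that the sets came from separate cultures. In total 25 gene lists with at least 5 measured members were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. For YPD against F1 the test with an estimated correlation took no membrane set block. A further 3 lists, of a-specific genes, alpha-specific genes and genes deleted in BY4742, served to check the strain labels. Each treated array was also set against the mock array of its own set with no test, giving 9 pairs. A gene lay at or below the background in an array when the mean background-subtracted signal of its spots was 0 or less, and no ratio is given for such genes among those named in a pair, a limit set after the values were seen. List medians of a pair were ranked among 10000 random lists matched on mean intensity in 20 bins. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for reading, the random lists and the figures.

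The comparisons, tests, gene lists, naming rule and most alternative settings were fixed before the data were examined. The rule named, for each dose contrast and for YPD against F1, up to 8 genes per direction with the largest change among those that passed and, for dose, went the same way in all 4 sets. Where fewer than 8 passed, the genes with the smallest p in that direction were given as values. It also named the 3 members of each list with the smallest p, the 5 genes per direction with the smallest p for the interactions, the 8 highest and lowest bright genes of each pair, and a fixed set that included RNR2, RNR3, RNR4, HUG1, MAG1, RAD54, DDR48, HSP12, PDR5 and SNQ2. HUG1 was not measured. Of the genes it took, the text gives those that bear on each group.

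Alternatives fixed in advance were median centring, cyclic loess, no background correction, 4 times the pseudocount, the series table, bright genes only, each membrane set left out, other blocks, fits of fewer arrays, the BY4742 pair added, no trend, other thresholds, the estimated correlation and fry. Settings chosen after seeing the data were the 30 min sets only, the 1 h sets only, a fit without the 30 min arrays at 0.0125%, and 2 further treatments of the membrane sets for YPD against F1. The fits were tested on simulated data with 6094 genes, of which 200 were changed. The noise was normal and independent between arrays, except where a block correlation was simulated. For 0.0125% against mock, 10 of 67 genes changed by 1 on the log2 scale were found, 56 of 67 changed by 2 and 66 of 66 changed by 4, with 8 false calls among 140. For YPD against F1, 61 of 251 calls were false. The block correlation estimated from 4 sets ran low there, at 0.0735 for a simulated 0.3 against 0.0744 in the data, and 10.2% to 12.8% of unchanged genes had an unadjusted p under 0.05.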

Results

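The series holds expression profiles of budding yeast after low-level MMS treatment on 14 membrane arrays, 1 per condition. FF18984 was measured as 4 mock, 4 low-dose (0.00125%) and 4 high-dose (0.0125%) arrays, spread over F1 and YPD medium at 30 min and 1 h, and BY4742 as 1 mock and 1 high-dose array in YPD at 1 h. Values are log2 intensities, and a difference of 1 is a 2-fold change. The median background-subtracted signal per array ran from 41.7 in the BY4742 mock array to 2018610 in the FF18984 high-dose array in YPD at 30 min. Among the FF18984 arrays the share of genes at or below the background was highest in the high-dose arrays at 1 h, at 31.4% in F1 and 33.4% in YPD, against 2.57% and 11.2% in their mock arrays. In BY4742 it was 8.05% at the high dose and 11.7% in mock. The number of arrays limits the precision, and no condition was replicated.

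The strain labels were checked on mating-type genes and on the marker genes deleted in BY4742, and most but not all of these genes went with the labels. STE2, the receptor for alpha-factor made by a cells, had a mean log2 intensity of 1.61 ± 0.53 (SD, n = 6) in FF18984 at 30 min and 2.48 ± 0.32 (SD, n = 6) at 1 h, against -2.15 and -1.65 in the BY4742 arrays. STE3, the receptor for a-factor made by alpha cells, was at -1.50 and -1.73 in FF18984 and at 1.90 and 1.29 in BY4742. Of the 7 a-specific genes, MFA1, MFA2, STE6, AGA2 and ASG7 were also higher in FF18984 at both times. AGA2 was at 0.11 ± 0.92 (SD, n = 6) at 30 min, against -0.30 and -0.70 in BY4742. BAR1 was at 1.08 and 0.95 in FF18984 and 0.97 and 0.73 in BY4742. Of the 4 alpha-specific genes, MF(ALPHA)1 was at -1.16 and -0.44 in FF18984 and 1.38 and 1.74 in BY4742. MF(ALPHA)2 was at 0.73 and -1.13 in FF18984 and 3.21 and 3.70 in BY4742. SAG1 was bright in FF18984 at 30 min (2.73) and in BY4742 (2.91 and 1.97) but not in FF18984 at 1 h (-1.13). Among the 4 marker genes deleted in BY4742, URA3 stood at 6.47 and 6.91 in FF18984 against 1.11 and 1.47, and LEU2 at 0.36 and 0.72 against -1.22 and -1.44. In BY4742 the mean percentile of LEU2 was 24.4, but that of URA3 was still 78.0. Of the other 2 markers, HIS3 did not separate the strains and so decides nothing about the labels. It was at 0.73 and 1.35 in FF18984 and 1.13 and 0.76 in BY4742. LYS2 went against the labels. It was higher in BY4742, at 4.25 and 3.72 or a mean percentile of 97.7, than in FF18984, at 2.89 at 30 min and -1.10 at 1 h. That is a strong signal for a gene that BY4742 lacks.

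The arrays fell into separate clusters. Across genes, which are not independent replicates, the FF18984 arrays correlated with a median of 0.799 within 30 min and 0.834 within 1 h, but 0.403 between the times. The BY4742 arrays, taken at 1 h, correlated with the FF18984 YPD arrays at 0.828 to 0.863 for 30 min and at 0.407 to 0.421 for 1 h.

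**Figure D1:**
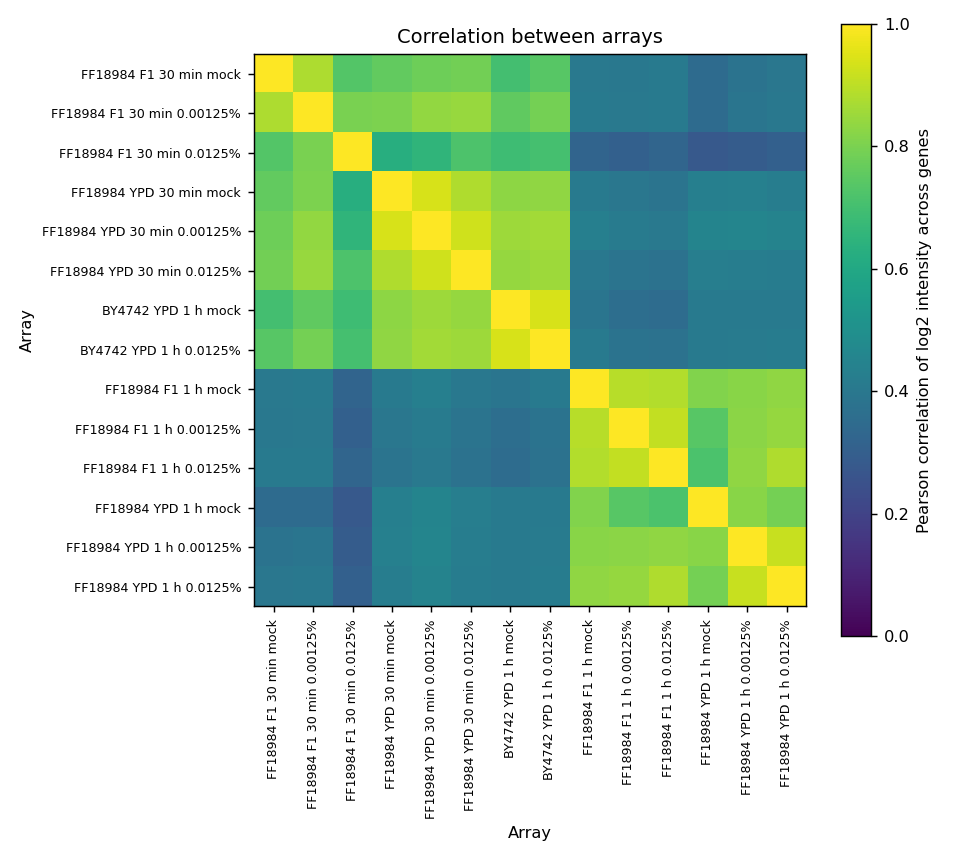
Pearson correlation of log2 intensity across genes for each pair of the 14 arrays, with the arrays on both axes and the correlation as colour from 0 to 1. The FF18984 30 min arrays and the BY4742 1 h arrays form a block, and the FF18984 1 h arrays another, with 0.279 to 0.456 between the FF18984 arrays of the 2 times.

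The high dose was compared with mock treatment to find the genes that respond to 0.0125% MMS in both media and at both times. Of the 3 genes that passed as higher, 2 encode subunits of ribonucleotide reductase, the enzyme that makes deoxyribonucleotides for DNA synthesis and repair. RNR2, a small subunit, rose by 2.62 ± 0.34 (SE, 4 sets) on the log2 scale, or 6.16-fold, and RNR1, the main large subunit, by 2.16 ± 0.35, or 4.46-fold. YNL134C, a predicted oxidoreductase, rose by 1.96 ± 0.32, or 3.88-fold. ACA1, a transcription factor of the ATF/CREB family, fell by 2.04 ± 0.32, and YOL106W, a dubious open reading frame, fell by 1.98 ± 0.33. All 5 went the same way in 4 of 4 sets, with limma adjusted p of 0.00974 for RNR2 and 0.0331 for each of the others. RNR2 was higher by 2.12 to 3.30 in the single sets. The signal of these 5 genes was above the background in all 12 arrays.

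In total 5 of 6094 genes passed at 0.0125% against mock, 3 higher and 2 lower, while 810 had an unadjusted p under 0.05 where chance gives 304.7. The count was 11 without the F1 30 min set and 0 without any 1 of the other 3 sets. It was 0 under median centring and with the series table, with RNR2 at 2.80 and 2.57 there, not past the threshold. With no background correction 2 genes passed, and RNR2 and RNR1 were at 1.53 and 1.03, not past the threshold. With the 30 min sets alone 32 genes passed, none of them among the 5, and with the 1 h sets alone 12, of which 3 were among the 5.

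Other genes, some with larger differences than RNR1, did not pass. RNR3, the damage-induced large subunit, was at 1.96 ± 0.42 and higher in 4 of 4 sets (adjusted p = 0.112), and RNR4, the other small subunit, at 1.02 ± 0.35 (adjusted p = 0.236). RPN2, a proteasome subunit, was at 1.999 (adjusted p = 0.103), and DAP1 (2.30), the translation initiation factor gene RPG1 (2.36) and OYE3, an NADPH oxidoreductase (1.70), each had an adjusted p of 0.112. On the lower side were SNZ3, of vitamin B6 synthesis (-2.01, adjusted p = 0.063), MTC7 (-2.84, adjusted p = 0.0644), the kinetochore gene DSN1 (-1.88, adjusted p = 0.0692), the histone methyltransferase gene DOT1 (-1.85, adjusted p = 0.103), and RGI2 (-1.40) and QCR8 (-1.41), both at 0.112. SNZ3 and DOT1 lay at or below the background in 3 of the 4 high-dose arrays, and DSN1 and RGI2 in 2. RNR3, RPN2 and RPG1 lay there in 1 of the 4 mock arrays, and the RNR3 difference ran from 0.59 to 2.33 under the alternatives. MAG1, the 3-methyladenine glycosylase, which lay at or below the background in 2 of the 4 high-dose arrays, was at -0.34, RAD54, of recombination, at -0.15, the stress genes DDR48 and HSP12 at 0.05 and -0.23, and the drug transporter genes PDR5 and SNQ2 at -0.43 and 0.88, none of them past the threshold.

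**Figure D2:**
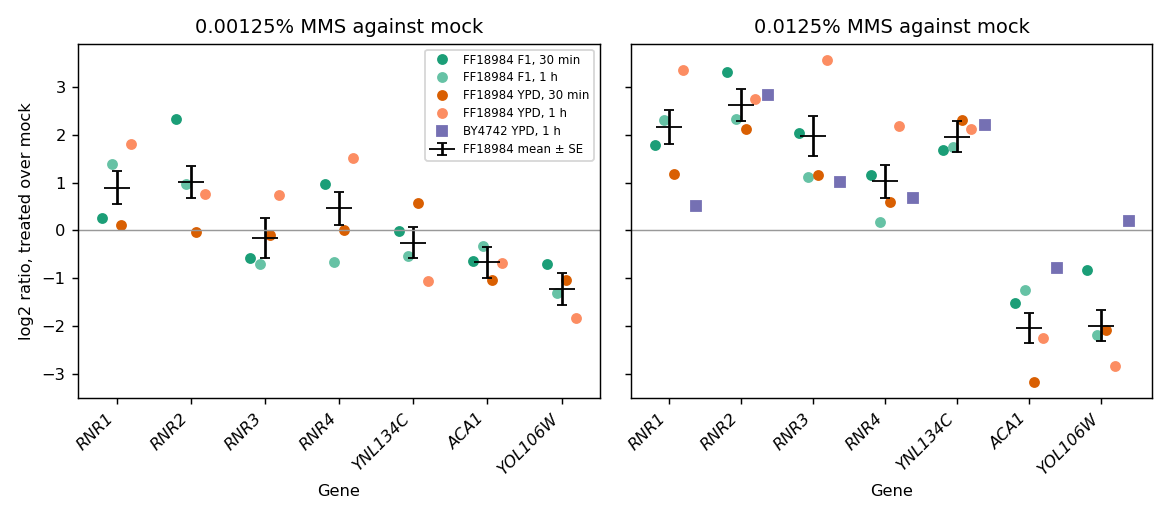
Log2 ratio of treated over mock arrays for the 4 ribonucleotide reductase genes and the other 3 genes that passed at 0.0125%, by membrane set (points), with the FF18984 mean and its SE (bars) and the BY4742 pair (squares). RNR2 averages 1.00 at 0.00125% and 2.62 at 0.0125%.

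Of the 25 gene lists, 5 passed at 0.0125% against mock by camera, 3 higher and 2 lower. Cytosolic ribosomal protein genes fell, with a median of -0.35 over 122 genes, 96 of them lower, and lower list medians in 4 of 4 sets (adjusted p = 1.29e-05). This call was lost, with adjusted p = 0.289 with an estimated correlation. The median was -0.16 under median centring and turned to 0.05 with the series table, which moved the median of all genes by 0.10, neither past the threshold, and no member passed over all genes or adjusted over the list alone. RPS27A was at -2.08 and RPP1B at -1.15. The 10 histone genes fell, with a median of -0.82, in 4 of 4 sets (adjusted p = 0.00918, and adjusted p = 0.289 with an estimated correlation). Of them 4 passed adjusted over the list alone and 0 over all genes, among them HTA2 (-0.99) and HTB2 (-1.04). Without the F1 30 min set the histone median was -0.24, and under median centring, cyclic loess and the series table it was -0.37, -0.54 and -0.30, none past the threshold. Proteasome genes rose by a median of 0.31 over 36 genes, in 4 of 4 sets (adjusted p = 0.00918, and adjusted p = 0.289 with an estimated correlation). Of them 6 passed adjusted over the list alone and 0 over all genes, with RPN2 (1.999), RPN7 (1.86) and RPT2 (1.47) the top 3 by p. Amino acid biosynthesis genes rose by a median of 0.30 over 53 genes, in 3 of 4 sets (adjusted p = 0.00918, and adjusted p = 0.289 with an estimated correlation). ASN1 was at 1.36 and LEU4 at 1.01, with 0 members past either threshold. Chaperone genes rose by a median of 0.46 over 20 genes, in 3 of 4 sets (adjusted p = 0.00972, and adjusted p = 0.289 with an estimated correlation), with SSB1, a ribosome-bound chaperone (2.65), the 1 gene past the threshold adjusted over the list alone and 0 over all genes.

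Thus 0 of the 5 calls held when the correlation between genes was estimated from the data. The 2 times also gave different lists. With the 30 min sets alone 3 passed, all lower, namely ribosomal proteins (-0.41), histones (-0.97) and glycolysis (-0.61). With the 1 h sets alone 3 passed, all higher, namely chaperones (0.85), amino acid biosynthesis (0.48) and glycolysis (0.84), and the proteasome passed in neither. Without the YPD 1 h set the proteasome (median 0.18), amino acid (median 0.06) and chaperone (median 0.13) calls ended. By fry, which tests whether a list's genes move 1 way and does not compare them with other genes, 5 lists passed. Of these, 2 were among the 5 of camera, the ribosomal proteins (adjusted p = 0.0345) and the proteasome (0.0401). The other 3 were oxidative stress and glutathione genes, higher (0.0345), and nucleotide excision and postreplication repair (0.0402) and G2 and M phase genes (0.0428), both lower.

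By camera the list of 21 DNA damage-inducible genes did not pass (adjusted p = 0.137), with a median of 0.03 and a mean of 0.33. Of its members 2 passed over all genes and 3, RNR1, RNR2 and RNR3, adjusted over the list alone. Among 26 oxidative stress and glutathione genes (median 0.10, adjusted p = 0.197), 3 passed adjusted over the list alone and 0 over all genes, namely OYE3, OYE2 (0.95) and YAP1, a transcription factor of the oxidative stress response (2.02). Among 36 respiration and TCA cycle genes (median 0.05, adjusted p = 0.927), 3 were lower adjusted over the list alone and 0 over all genes, namely QCR8, CYC1 (-1.25) and QCR7 (-1.24). In the other repair lists 0 genes passed either threshold. Their medians were -0.33 for base excision and alkylation repair (adjusted p = 0.12), -0.30 for nucleotide excision and postreplication repair (0.137), 0.28 for homologous recombination (0.197) and 0.24 for the DNA damage checkpoint (0.388). The remaining lists did not pass by camera either. Their medians were -0.41 for G2 and M phase genes (adjusted p = 0.121), -0.09 for G1 and S phase genes (0.369), 0.39 for purine and one-carbon synthesis (0.102), 0.02 for pyrimidine synthesis (0.855), 0.18 for ribosome biogenesis (0.135), -0.12 for mitochondrial ribosomal proteins (0.78), 0.12 for sulfur and methionine metabolism (0.145), 0.08 for glycolysis and fermentation (0.302), 0.13 for environmental stress genes (0.321), 0.20 for drug transporters (0.388), 0.19 for iron uptake (0.459), -0.09 for ergosterol synthesis (0.664) and -0.08 for phosphate genes (0.918).

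**Figure D3:**
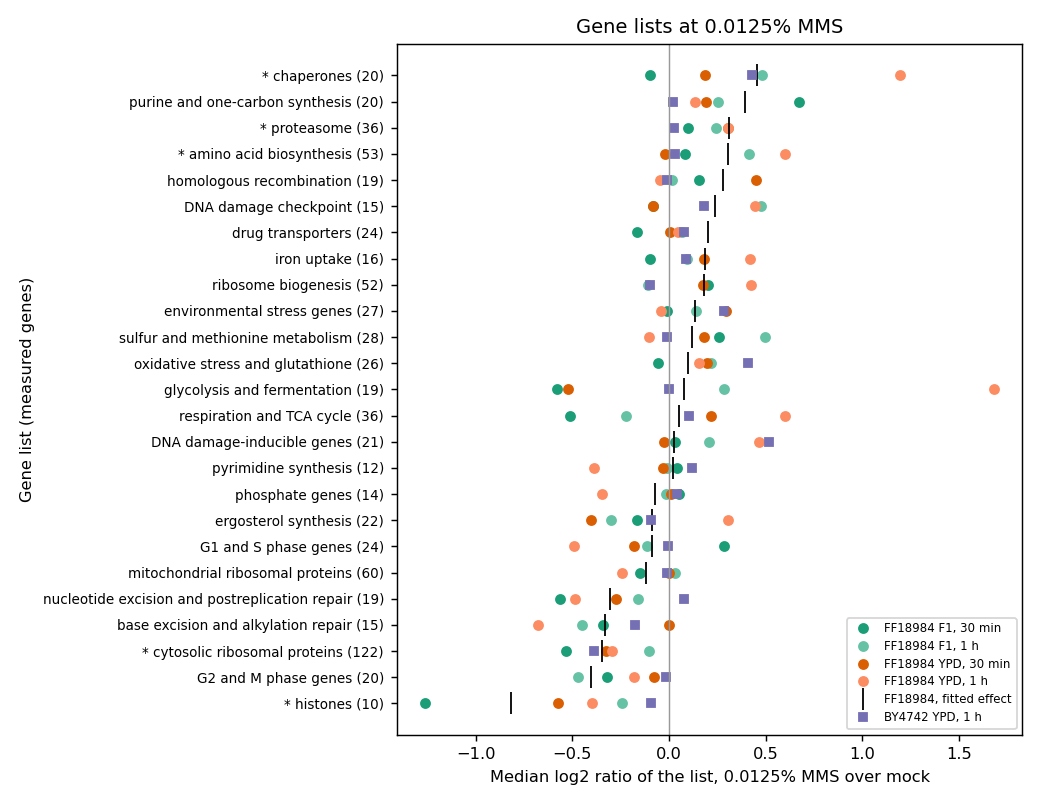
Median log2 ratio of 0.0125% MMS over mock of each gene list, by FF18984 membrane set (points) and in the BY4742 pair (squares), with the median of the fitted FF18984 effects (bar), which can lie outside the set medians, and an asterisk at lists past the threshold. The ribosomal protein and histone lists lie below 0 in all 4 sets and the proteasome list above 0, although the ribosomal protein median is 0.05 with the series table.

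At the low dose of 0.00125% no gene could be told from mock. RNR2 was at 1.00 ± 0.34 and higher in 3 of 4 sets (adjusted p = 0.697), RNR1 at 0.90 ± 0.35 and higher in 4 of 4 (adjusted p = 0.724) and RNR3 at -0.15. PMA1, the plasma membrane proton pump (1.82), and SEG2 (1.43) were among the highest by p, and YLR334C (-1.72) was among the lowest. By limma 0 of 6094 genes passed, and 392 had an unadjusted p under 0.05 where chance gives 304.7. On simulated data of this design, with independent normal noise, 56 of 67 genes changed by 2 on the log2 scale were found at the low dose. The share may be lower in the data, where DAP1, RPG1, MTC7 and SSB1 differed by more than 2 at the high dose and did not pass. Glycolysis and fermentation genes rose by camera, with a median of 0.52 over 19 genes, 16 of them higher, and a median above 0 in 3 of 4 sets (adjusted p = 0.00822, and adjusted p = 0.728 with an estimated correlation). HXK2, a hexokinase, was at 1.29 and PDC5, a pyruvate decarboxylase, at 1.04. Chaperone genes rose by a median of 0.26 over 20 genes, in 3 of 4 sets (adjusted p = 0.0458, and adjusted p = 0.728 with an estimated correlation), with SSA2 at 0.89. No member of either list passed over all genes or adjusted over the list alone. Neither list call held with the estimated correlation, and by fry 0 lists passed. The glycolysis median came from the YPD 1 h set, at 1.45 against 0.00 to 0.11 in the others, and 11.2% of genes in its mock array and 23.1% in its low-dose array were at or below the background. Without that set the medians were 0.21 and 0.13 and 0 lists passed, and without the YPD 30 min set the chaperone call ended (median 0.22).

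Between the 2 doses, YLR162W, a small protein of unknown role, was 2.33 ± 0.35 higher at 0.0125% than at 0.00125% and YNL134C 2.21 ± 0.32 higher, each in 4 of 4 sets with an adjusted p of 0.0335. These 2 genes of 6094 passed, with 326 at an unadjusted p under 0.05 and 304.7 given by chance, and the count was 0 without any 1 of the 4 sets. MEF1, a mitochondrial translation factor (2.20, adjusted p = 0.0607), CDD1, a cytidine deaminase (2.29, adjusted p = 0.069), RNR3 (2.12, adjusted p = 0.197) and RNR2 (1.62, adjusted p = 0.224) did not pass. The RNR3 value ran from 0.63 to 2.41 under the alternatives. By camera 4 lists passed. Cytosolic ribosomal proteins fell, with a median of -0.24, in 4 of 4 sets (adjusted p = 2.15e-07, and adjusted p = 0.184 with an estimated correlation). Histones fell, with a median of -0.65, in 4 of 4 sets (adjusted p = 0.00229, and adjusted p = 0.241 with an estimated correlation). Proteasome genes rose by a median of 0.22, in 4 of 4 sets (adjusted p = 0.000287, and adjusted p = 0.184 with an estimated correlation). Of them 6 passed adjusted over the list alone and 0 over all genes, with RPN2 at 1.62. Oxidative stress and glutathione genes rose by a median of 0.29, in 4 of 4 sets (adjusted p = 0.0474, and adjusted p = 0.204 with an estimated correlation). By fry the histones did not pass (adjusted p = 0.207) and the other 3 lists did.

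The time of sampling was tested as an interaction with the high dose. The effect of 0.0125% MMS differed between 1 h and 30 min for 14 genes, 5 higher and 9 lower at 1 h, with 1043 genes at an unadjusted p under 0.05. All 14 had the larger effect at 30 min. MRPL25, a mitochondrial ribosomal protein gene, was at 2.97 at 30 min and -1.47 at 1 h, a difference of -4.44 ± 0.60 (adjusted p = 0.0234). For CDC39, of the CCR4-NOT complex, the difference was -3.72 ± 0.61, for TSC11, of TOR complex 2, -5.28 ± 0.89, for AIM45 -3.14 ± 0.52 and for TED1 -4.15 ± 0.70. Higher at 1 h were TIR2, a cell wall mannoprotein gene (4.46 ± 0.81), ERR2, an enolase-related gene (4.11 ± 0.70), RET2, a coatomer subunit (4.01 ± 0.70), YDR535C (3.18 ± 0.57) and SCJ1, a chaperone of the endoplasmic reticulum (3.08 ± 0.55), which was at -0.50 without background correction. MRPL25 and TED1 lay at or below the background in both high-dose arrays at 1 h, TSC11 in 1 of them, and ERR2 in both mock arrays at 1 h. YDR535C lay there in all 3 YPD arrays at 1 h, so neither array behind its ratio in that set was above the background. The sizes of the differences of these 5 genes thus depend in part on the pseudocount. With 4 times the pseudocount ERR2 was at 2.22 and not past the threshold. Each of the 9 genes named after MRPL25 had an adjusted p of 0.0452, and in each the single sets were higher in 2 and lower in 2 of 4. The count was 158 without the YPD 30 min set, 0 without any 1 of the other 3 sets, 447 under median centring, which moved the median of all genes by 0.39, and 0 under cyclic loess. For the low dose 0 genes differed between times by limma, with 510 at an unadjusted p under 0.05.

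By medium, 0 genes had a 0.0125% effect that differed between YPD and F1 by limma, with 253 at an unadjusted p under 0.05 and a smallest adjusted p of 0.953, and 4 passed without the F1 1 h set. TIR1, a cell wall mannoprotein gene, had the smallest p of the positive differences, at 3.09 ± 0.70. For the low dose the count was 0, with 116 at an unadjusted p under 0.05. On simulated data 13 of 67 genes whose effect differed between media by 2 on the log2 scale were found.

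YPD was compared with F1 to find the genes that differ with growth medium in FF18984 cells. Cytosolic ribosomal protein genes were higher in YPD than in F1 by a median of 1.44 over 122 genes, of which 84 passed over all genes and 106 adjusted over the list alone (camera adjusted p = 0.0309 with an estimated correlation and no membrane set block). These counts fell to 31 and 98 with the block correlation calibrated on simulated data and to 36 and 88 with the means of the 4 membrane sets as the unit. The list median lay between 1.00 and 1.83 in the 6 pairs of arrays matched on time and dose. Each membrane set holds 1 medium, so these 6 pairs come from 2 sets per medium and are not 6 independent replicates. RPL26B was higher by 2.43 ± 0.32 (SE, 6 arrays in 2 sets per medium) and RPL22A by 2.43 ± 0.32, each in 6 of 6 pairs. MET6, the methionine synthase gene, fell by 4.67 ± 0.39 from F1 to YPD. Other single genes among the 8 with the largest falls were ZRT1, a zinc transporter gene, at -3.46 ± 0.49, ZPS1, a zinc-regulated gene, at -3.63 ± 0.38, the amino acid permease genes AGP1 and GAP1 at -3.11 ± 0.37 and -2.95 ± 0.54, and MEP2, an ammonium transporter gene, at -2.80 ± 0.44. GAP1 was at -1.08 in the 30 min arrays and -4.82 in the 1 h arrays, and MEP2 at -1.80 and -3.80.

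Of 6094 genes 320 passed, 201 higher and 119 lower in YPD, with 1241 at an unadjusted p under 0.05. With the means of the 4 membrane sets as the unit 136 genes passed, of which 124 were among the 320. The lowest adjusted p were 1.41e-05 for MET6 and 0.000161 for ZPS1, both lower in 6 of 6 pairs. Among the 8 genes with the largest rises were PKR1, of vacuolar ATPase assembly, at 3.74 ± 0.60 (adjusted p = 0.00226, 6 of 6 pairs), RRS1, of ribosome biogenesis (3.10), AIM33 (2.97), the asparaginase gene ASP3-2 (2.60), RPL9A (2.48) and RSC1, a chromatin remodeller subunit (2.36). Their order differed between the sampling times. In the 30 min and in the 1 h arrays PKR1 was at 1.78 and 5.69, RRS1 at 0.99 and 5.22, AIM33 at 1.79 and 4.15, ASP3-2 at 3.54 and 1.66 and RPL9A at 3.29 and 1.67, and RRS1 did not pass without either 1 h set, nor AIM33 without the YPD 1 h set. PKR1 and AIM33 lay at or below the background in 3 of the 6 F1 arrays and RRS1 in 5, and PYC1, AGP1, SCL1 and FIT2 in 3 of the 6 YPD arrays and GTT1 in 4, so the sizes of these differences depend in part on the pseudocount. PYC1, a pyruvate carboxylase (-3.24), and the vacuolar protease gene PRB1 (-2.79) were among the 8 lowest. On simulated data this test called too many genes, with 61 false of 251 calls, and with the block correlation that gives the estimate in such data 75 genes passed, 44 higher and 31 lower. AIM33 and RPL9A were not among them. The count was 10 with the 4 mock arrays alone. It was 136 without the YPD 30 min set, 552 without the F1 1 h set and 770 without the YPD 1 h set, but there the block correlation was set to 0, so that arrays of 1 set counted as independent.

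By camera 5 lists passed for YPD against F1. The ribosomal protein list (adjusted p = 4.49e-60, median above 0 in 6 of 6 pairs) was the 1 past the threshold with an estimated correlation, at adjusted p = 0.0309. That test took no membrane set block, so it counted the 6 arrays of a medium as independent, although they come from 2 sets. Amino acid biosynthesis genes fell, with a median of -0.57 over 53 genes, in 6 of 6 pairs (adjusted p = 4.03e-05, and adjusted p = 0.128 with an estimated correlation). Of them 6 fell over all genes and 11 adjusted over the list alone, among them HIS4 (-2.08), LEU1 (-2.09) and LEU4 (-1.59), which was at -1.04 in the 1 h arrays. Sulfur and methionine genes fell, with a median of -0.35 over 28 genes, in 6 of 6 pairs (adjusted p = 0.00419, and adjusted p = 0.128 with an estimated correlation). Of them 6 were lower over all genes and 8 lower and 1 higher adjusted over the list alone, with lower ones such as MET10, a sulfite reductase subunit (-2.64), and MET17 (-1.99). Respiration and TCA cycle genes fell, with a median of -0.48 over 36 genes, in 5 of 6 pairs (adjusted p = 0.00207, and adjusted p = 0.16 with an estimated correlation), with the aconitase gene ACO1 (-1.71) the 1 that passed over all genes and adjusted over the list alone. Proteasome genes fell, with a median of -0.31 over 36 genes, in 6 of 6 pairs (adjusted p = 0.0322, and adjusted p = 0.163 with an estimated correlation), with SCL1 (-2.09), RPN2 (-1.79) and RPT6 (-1.68) the 3 that passed over all genes and 7 lower adjusted over the list alone. The respiration call ended without the F1 1 h or the YPD 1 h set (median -0.31 in each), the sulfur call without the F1 30 min set (median -0.37) and the proteasome call without any 1 of the 4 sets (medians -0.35 and -0.22). With the means of the membrane sets as the unit 4 lists passed, without the proteasome (adjusted p = 0.0719). With the calibrated block correlation the members past the threshold over all genes fell from 6 to 1 for amino acid biosynthesis, from 6 to 2 for sulfur and methionine and from 3 to 1 for the proteasome, and LEU1, LEU4, MET10, RPN2 and RPT6 did not pass.

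Outside the lists that passed, iron uptake genes had a median of -0.39 over 16 genes (adjusted p = 0.072) and 3 lower and 1 higher over all genes and adjusted over the list alone. The lower ones were the ferroxidase gene FET3 (-1.84), FTR1 (-1.47) and the mannoprotein gene FIT2 (-2.31), each in 6 of 6 pairs. The 12 pyrimidine synthesis genes went both ways, with a median of 0.18 and a mean of -0.04 (adjusted p = 0.998). URA2 (-2.29, and -1.28 in the 1 h arrays) and URA1 (-1.39) were lower over all genes and CDC8, the thymidylate kinase gene, was higher (1.11, adjusted p = 0.0335), and adjusted over the list alone 3 were higher and 2 lower. Of the 26 oxidative stress and glutathione genes (median -0.19, adjusted p = 0.39), GTT1, a glutathione transferase gene (-2.37), was lower over all genes, and of the 14 phosphate genes (median 0.46, adjusted p = 0.0847) SPL2, a phosphate-responsive gene, was higher (1.44). FTR1, URA1, CDC8 and SPL2 did not pass with the calibrated block correlation. By fry 10 lists passed, the 5 of camera and those of iron uptake (adjusted p = 0.000977), phosphate (0.00537), environmental stress (0.0147), G2 and M phase (0.017) and oxidative stress and glutathione genes (0.0252). RNR2 was at 0.13, which did not pass (adjusted p = 0.86).

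Each treated array was also compared with the mock array of its own membrane set, without replicates and so without a test. Between 529 genes (YPD 30 min, 0.00125%) and 2224 genes (F1 30 min, 0.0125%) differed by 2-fold or more in FF18984, and 550 did in BY4742, 314 higher and 236 lower. With 4 times the pseudocount the median count per pair moved from 1226 to 291. Of the 144 bright genes named as highest or lowest in the 9 pairs, 47 lay at or below the background in 1 array of the pair, and no ratio is given for them. In YPD at 1 h with 0.0125% MMS the others among the highest included PMP2, a proteolipid gene (4.36), and the cell wall genes HSP150 (4.31) and SED1 (4.12). All 3 were also among the highest there at 0.00125%, at 4.64, 4.76 and 3.37, but both ratios use the same mock array, so this is no repeat. That mock array correlated with the low-dose and high-dose arrays of its set at 0.824 and 0.793, while these correlated at 0.914 with each other. In F1 at 1 h with 0.0125% they included CYS3 (2.42), RNR2 (2.33) and RNR1 (2.30), and the 8 lowest all lay at or below the background in the treated array. The 30 min pairs at 0.0125% had SSB1 (6.004) and TSC11 (5.26) among the highest in F1 and YAP1 (4.32) in YPD. Among the lowest were TIR2 (-3.61) and HYP2, a translation factor gene (-3.53), in F1 and MTC7 (-4.74) and HYP2 (-4.71) in YPD. Both of these pairs hold an array with limits. The F1 30 min mock array had the lowest correlation between the spots of a pair, at 0.675. In the YPD 30 min array at 0.0125% the background made up 87.3% of the spot integral. At 0.0125% the glycolysis median was -0.58 in F1 at 30 min, -0.52 in YPD at 30 min, 0.29 in F1 at 1 h and 1.68 in YPD at 1 h, and the chaperone median was -0.10, 0.19, 0.48 and 1.19. Both YPD 1 h medians exceeded those of all 10000 random lists, and 33.4% of genes in that treated array were at or below the background.

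The BY4742 pair was used to see which responses of FF18984 appear in a second strain. RNR2 was 2.83 higher with 0.0125% MMS than in mock and YNL134C 2.21 higher, at the 99.95 and 99.79 percentiles of all genes. RNR1 (0.52), RNR3 (1.01) and RNR4 (0.68) were higher by less, ACA1 was at -0.79 and YOL106W at 0.20. MAG1 was at 1.09, RAD54 at 1.30 and HSP12 at -1.13 in this pair. Of the bright genes above the background in both arrays, the highest included TRK2, a potassium transporter gene (3.30), and MNT2 (2.34), and the lowest SSK2 (-3.36), GAS1 (-2.85) and PMA1 (-2.64). The median of DNA damage-inducible genes was 0.52, at the 99.9 percentile of random lists, that of oxidative stress and glutathione genes 0.41, and that of environmental stress genes 0.28. Of the 5 lists called in FF18984, chaperones had a median of 0.43 and ribosomal proteins of -0.39, at the 99.8 and 0 percentiles, whereas the proteasome (0.03), amino acid biosynthesis (0.03) and histones (-0.09) lay at the 65.9, 79.3 and 32.0 percentiles. Across all genes, which are not independent replicates, the BY4742 ratio correlated with the 4 FF18984 pairs at 0.0125% at -0.094, 0.0274, 0.0576 and 0.0702. Of the 810 genes at an unadjusted p under 0.05 in FF18984, 417 (51.5%) had the same direction in BY4742. With 1 pair, the difference between strains was not tested.

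The effects of the 2 doses correlated across genes at 0.632, where simulated unchanged groups with a shared simulated mock group gave 0.499 ± 0.0097 (SD over 100 simulations). The covariance was 0.161 against 0.0773 simulated. The simulation gave mock and treated arrays the same spread. Mock arrays that spread more would raise both values without a shared response, so the comparison cannot tell the 2 apart. The F1 30 min mock array had the lowest correlation between the spots of a pair, at 0.675. With the low dose taken from 2 sets and the high dose from the other 2, which share no mock arrays, the correlation was -0.0463 to 0.205 over the 6 ways of dividing the sets.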

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

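The tests of sampling time, plate layout, spot identity, loss of signal, normalization, dim signal on the 1 h membranes and time in MMS were chosen only after the result was seen. The intensity-matched random lists and the other splits of the samples were chosen before.

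The first pattern is the weak correlation between the 30 min and the 1 h arrays of FF18984. Sampling time as its cause is argued against by BY4742, sampled at 1 h, whose arrays correlated with the FF18984 YPD arrays of 30 min by 0.436 more than with those of 1 h. Plates laid out differently are argued against by the layout in the files, which correlated best in 18 of 18 plates among 1536 layouts each. That most spots stand for other genes on 1 kind of membrane is argued against by the differences between YPD and F1, which correlated across genes at 0.256 between the times. This cannot exclude a share of such spots. LYS2 was at mean percentile 88.6 in FF18984 at 30 min, 97.7 in BY4742 and 29.8 in FF18984 at 1 h, and SAG1 at 92.0, 89.8 and 28.9. STE2, STE3, URA3 and LEU2 went with the strain instead. What stays open is a share of spots that stand for other genes, or a membrane kind or an array processing that differs between the times. The labels give none of these, and each may carry part of any difference between 30 min and 1 h.

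The second pattern is the lower cytosolic ribosomal protein list at 0.0125% MMS. A bias shared by genes of like intensity is argued against, in the quantile-normalized values only, by the list's median. It lay at percentile 0 of 10000 random lists matched on intensity. Genes of a random list need not move together as those of this list may, so the percentile is not a p-value for the fall. Loss of signal in the 1 h sets as the cause is argued against by the 30 min sets, whose list medians were the lower ones, with a difference of -0.030 between the higher at 30 min and the lower at 1 h. A shift set by the normalization stays open and may account for the call, since 1 of 3 other scalings kept it, and the median moved from -0.35 to -0.16 under median centring, -0.34 under cyclic loess and 0.05 with the series table. A response of the cells to MMS stays open too.

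The third pattern is the 14 genes whose 0.0125% effect differed between 1 h and 30 min by the test of the interaction. The differences of 1 h minus 30 min were 4.11 for ERR2, 4.01 for RET2, 3.08 for SCJ1, 3.18 for YDR535C, 4.46 for TIR2, -4.44 for MRPL25, -3.14 for AIM45, -3.72 for CDC39, -5.28 for TSC11, -4.15 for TED1, -4.16 for BPL1, -3.89 for ESP1, -4.46 for CCH1 and -4.64 for KIC1. A signal near the background on the 1 h membranes and the time in MMS cannot be told apart, since 8 of the 14 genes lay below the median gene there. The 30 min arrays have limits too, which were not tested as a cause. Their F1 mock array had the lowest correlation between the spots of a pair, at 0.675. In their YPD array at 0.0125% the background made up 87.3% of the spot integral. The BY4742 pair decides nothing, as all 14 genes had the larger effect at 30 min, so that a ratio near 0 mostly lies nearer to the 1 h mean, as the BY4742 ratio did in 13 of 14. The 4 sets can be divided in 3 ways, too few for a share under 0.05, and the real count was 14 against at most 0 in the others (1 of 3 ways as large). Leaving out the YPD 30 min set gave 158 genes and leaving out any 1 of the others gave 0.

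Other splits exchanged the dose labels within each membrane set. For 0.0125% against mock, 1 of 100 splits, the real one, gave as many as 5 genes, with at most 1 in the others. This argues against a chance assignment of the dose labels for the count, not for any single gene. Such splits cannot address what goes with dose within a set, such as the order of hybridisation, which is not given. For 0.0125% against 0.00125% it was likewise 1 of 100, with 2 genes against at most 0. At 0.00125% all 100 splits gave at least the real count of 0, and the highest was 1. For the gene lists chance cannot be excluded. As many as the 5 lists at 0.0125% were found in 6 of 100 splits and as many as the 2 lists at 0.00125% in 37 of 100, with at most 6 in the others for each. The sets themselves divide in only 3 ways, too few for a share under 0.05. The real count for YPD against F1 was 320 genes and the highest other 3139, for 30 min against 1 h (2 of 3 ways as large), which points to the structure of the samples described above. The lists for YPD against F1 numbered 5 against at most 1 (1 of 3 ways as large), and the genes whose 0.0125% effect differed between media numbered 0 against at most 14 (3 of 3 ways as large).

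A sample stood far from the other 3 in 7 of 130 groups of 4, where chance flags about 1 in 20 groups. The glycolysis median at 0.00125% in the YPD 1 h set was 1.45 against 0.00 to 0.11 in the others, and the phosphate median at 0.0125% there was -0.35 against -0.01 to 0.05. The 0.0125% array in YPD at 30 min had a median signal of 2018610, a 90th percentile of 6860290 and a median of 58986.5 at empty positions, against at most 6230, 50685.4 and 825 in the other high-dose arrays. Of its strongest genes 1.31% followed the series table in a straight line, against 99.7% to 99.8% in the others, and in the mock group the YPD 30 min array stood apart at 99.8% against 99.7%.

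Spots outside the open reading frames included 86 positions for Ty retrotransposons, which no comparison used. Their log2 ratio to mock was taken without quantile normalization and less the median gene ratio of the pair. Its mean was above 0 in FF18984 in F1 at 30 min with 0.0125% (0.26), in F1 at 1 h with 0.00125% (0.54) and 0.0125% (0.80), and in YPD at 1 h with 0.00125% (0.67) and 0.0125% (0.67). It was -0.07, -0.13 and -0.12 in the other FF18984 pairs and -0.17 in BY4742.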

How the results depend on the processing

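The 30 min sets alone, the 1 h sets alone, the fit without the 30 min arrays at 0.0125%, the block correlation calibrated on simulated data and the set means were chosen only after seeing the data, and the other settings before. Of 9331 values of single genes, lists and pairs under alternatives, 8741 stayed on their side of the threshold or, for counts of a pair, close in size. Values that passed in neither fit counted there whatever their direction, and RNR3 for YPD against F1 kept its sign in 13 of 19. A further 358 no longer passed, 202 newly passed and 4 reversed. The 26 that moved were counts of genes at 2-fold in a pair. Counts of genes and lists per test are not among these and are given below. For each change below the cause was not tested, except that fewer sets or arrays give fewer degrees of freedom. With 3 sets the block correlation of the medium fit was set to 0, and with 1 time alone each medium is 1 set, so in both the arrays of a set stand in as replicates and the counts for YPD against F1 say nothing about stability. Genes at 0.00125% against mock numbered 0 under all 20 alternatives. The correlation between doses (0.605 to 0.682) and that of BY4742 with FF18984 (0.0289 to 0.061) moved by less than their spread. Signal over background limits the 1 h sets, where up to 33.4% of genes were at or below background.

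Genes at 0.0125% against mock numbered 5, and 0 under median centring, the series table, no set block and the 8 arrays alone, 1 under cyclic loess, a random block and no trend, 2 with no background correction, with the BY4742 pair added and without the 30 min arrays at 0.0125%, 8 at an adjusted p under 0.1, 20 from ratios per set, 32 with the 30 min sets alone, 12 with the 1 h sets alone, and 0 to 11 with a set left out. Genes between the doses numbered 2, and 0 under median centring, cyclic loess, the series table, no set block, the 1 h sets alone and without the 30 min arrays at 0.0125%, 1 with no background correction, 4 times the pseudocount and the 8 arrays alone, 4 at an adjusted p under 0.1, 6 from ratios per set, 15 with the 30 min sets alone, and 0 to 0 with a set left out. Genes whose 0.0125% effect differed by time numbered 14, and 447 under median centring, 0 under cyclic loess and no trend, 46 with no background correction, 2 with the series table, 8 among bright genes, 68 at an adjusted p under 0.1, and 0 to 158 with a set left out. By medium they numbered 0, and 0 to 4 with a set left out. In the test of time, median centring moved the median of all genes by 0.39 and the series table by 0.21. In that of medium, median centring and cyclic loess moved it by -0.15 and -0.11, and at 0.0125% against mock the series table moved it by 0.10.

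Genes for YPD against F1 numbered 320, and 201 with no background correction, 495 with no set block, 10 with the 4 mock arrays, 586 at an adjusted p under 0.1, 672 with the 30 min sets alone, 506 with the 1 h sets alone, 75 with the calibrated block correlation, 136 with set means, and 136 to 770 with a set left out. The balance of higher and lower genes moved from 201 and 119 to 204 and 249 under cyclic loess and 337 and 80 with the series table. Gene lists at 0.0125% numbered 5, and 0 with an estimated correlation, 3 with the 30 min sets alone, 3 with the 1 h sets alone, and 2 to 6 with a set left out. The 3 at 30 min were all lower and the 3 at 1 h all higher, and each shared 2 with the 5, ribosomal proteins and histones at 30 min and chaperones and amino acid biosynthesis at 1 h. Lists at 0.00125% numbered 2, and 5 under median centring, 1 with 4 times the pseudocount and among bright genes, 0 with an estimated correlation, with fry and with the 30 min sets alone, and 0 to 2 with a set left out. Lists for YPD against F1 numbered 5, and 8 under cyclic loess and without the 30 min arrays at 0.0125%, 3 with the series table and with the 30 min sets alone, 1 with an estimated correlation, 10 with fry, and 3 to 7 with a set left out. The median number of genes at 2-fold per pair was 1226, and 291 with 4 times the pseudocount, 527 among bright genes and 450 with the series table.

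Reversed were the cytosolic ribosomal proteins, 0.00125% vs mock, under median centring (0.25), SCJ1 (-0.50, difference by time) and RAD28 (-0.094, YPD against F1) with no background correction, and glycolysis and fermentation, 0.0125% vs mock, with the 30 min sets alone (-0.61); the cause was not tested.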

Other observations

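The test of the Ty spots was chosen before the result was seen. The Ty ratios given here are again less the median gene ratio of the pair. Of the Ty families, the 29 TY1A positions had mean log2 ratios to mock of 0.62 and 0.88 in F1 at 1 h and 0.70 and 0.89 in YPD at 1 h at the low and the high dose, and the 31 TY1B positions 0.58, 0.80, 0.59 and 0.50. In the BY4742 pair they were at -0.23 and -0.09. A response of Ty elements to MMS as a hypothesis is argued against as a general effect, since the mean ratio of the 86 positions was above 0 in 3 of 5 pairs at 0.0125%, and the BY4742 pair at the same time and in the same medium was at -0.17. Without that subtraction the mean log2 level of the 1 h Ty spots was -0.58 in mock, -0.40 at 0.00125% and -0.59 at 0.0125% in F1, and -0.65, -0.28 and -0.59 in YPD. The low dose was thus above mock in both media, while the high dose was close to mock. The high-dose ratios of the 86 positions, 0.80 in F1 and 0.67 in YPD, came mostly from a fall of the median gene of the pair.

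The 0.0125% log2 ratios of F1 and YPD correlated across genes at 0.182 at 30 min and 0.449 at 1 h, and between the times at -0.0343 to 0.0146. At an unadjusted p under 0.05, 810 genes at 0.0125% compare with at most 662 and a median of 236 in the other splits, and 392 at 0.00125% with at most 767.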
